A study of Mus musculus with 2 samples.

How the data were processed

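Per the file headers, the deposited files hold counts of unique molecular identifiers (UMIs) for 32285 genes in each barcode, made by the authors with the Cell Ranger pipeline on the mm10 mouse genome. The submitters' processing notes give version 7.1.0 of that program, and the file header gives 7.0.1. Whether intronic reads were counted and how barcodes were called is not stated. Positions came from GENCODE M21 on GRCm38, in which 32158 of the 32285 identifiers were found.

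Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept, which left out 109 of 3084 sham and 112 of 3299 nephrectomy barcodes. Scrublet scored doublets per library, but its own threshold called 0 nuclei. A rule chosen after seeing the data replaced it. Nuclei that scored above the limit of the highest 3% in their library were removed (165 in all, fewer than 3% because of tied scores), as were whole clusters with at least 20% such nuclei, which were 2 clusters with 218 nuclei. In total 147 sham and 134 nephrectomy nuclei were left out.

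The libraries were clustered together, with no centring, on 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1. Mitochondrial and ribosomal genes and every member of 34 fixed gene lists (663 genes, of which 656 were used) were kept out of the clustering genes. Clusters were named from fixed markers of 24 cell types. A name needed at least 3 markers at least 2-fold over the reference level and in at least 5% of its nuclei, and no other class with more markers among the cluster's top 10 genes. A cluster with a median depth under 1/3 of its libraries' medians also needed more of its own markers there than of any other class. The naming rule, the merging of related types and the splitting of 2 clusters with close scores were revised after looking at the data. Of 37 clusters, 4 stayed unnamed, and 8 classes with at least 30 nuclei in each library were compared. Class names mean nuclei like that type by these markers.

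UMIs were summed over the nuclei of a class and divided by the class total to give UMIs per 1000000 (CPM). The ratio of nephrectomy to sham CPM has an exact conditional binomial interval, summed counts an exact Poisson interval, shares an exact Clopper-Pearson interval and differences of shares a Newcombe interval, all at 95%. Gene list medians used members with at least 20 UMIs over both libraries in the class, and a percentile among 10000 random lists of the same size matched on mean expression describes these libraries only. Members were counted as higher or lower at a ratio of at least 1.5 either way. A count under 3 was set to 3 when genes were ranked and list medians taken. The median log2 ratio of all genes was at most 0.0626 in any class, so no shift was subtracted.

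Named genes followed a rule: with at least 100 UMIs in the class (300 in the whole library) and a ratio of at least 2 either way, the 10 highest and the 10 lowest were eligible, without predicted genes. Outside proximal tubule-like nuclei a gene also had to reach the whole-library CPM in its class, to leave out free RNA. Csgalnact1, Vcan and the 2 highest and 2 lowest members of each list could be named in any class. Genes of the lists added for the tests, and Xist, are exceptions, and any other gene is said to have been chosen after its values were seen. Some genes that met the rule are not reported here. Lists, markers, filters, the naming rule for genes and 16 of the 18 alternatives were set before the data were examined.

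To separate depth from expression, each nucleus was thinned to 1000 UMIs, which left out 318 sham and 277 nephrectomy nuclei. Free RNA was estimated from the UMIs of another class's markers, as the share of the library's own profile that explains them. It came to 20.1% of UMIs in sham and 15.1% in nephrectomy proximal tubule-like nuclei, 14.7% and 16.6% in endothelial-like nuclei and 9.39% and 8.58% in thick ascending limb-like nuclei. The method was tested on simulated data: genes set 2-fold and 4-fold either way all passed 1.5-fold in a simulated whole library and no unchanged gene did. In a class with 1/50 of the UMIs 92% of the genes set 2-fold higher and 1.41% of unchanged genes did. The simulated counts were independent Poisson draws from 1 pooled profile. Uneven spread over nuclei and variation between mice were not simulated, so this covers counting error only.

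Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors. No test across animals was possible with 1 library per group, and no p-value is given.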

Results

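Single-nucleus RNA sequencing on the 10x Genomics Chromium system was used to profile frozen kidney from male mice. The study asked how the remnant kidney left by 5/6 nephrectomy, a surgical model of progressive renal scarring, differs from a sham-operated kidney, with attention to Csgalnact1 and versican. In the model 1 kidney was removed and the poles of the remaining kidney were tied off a week later, and tissue was taken 4 weeks after surgery. Each group consisted of 1 library. The sham library held 3084 barcodes and 21365116 unique molecular identifiers (UMIs), with a median of 5140 UMIs per barcode and a range of 500 to 83191. The nephrectomy library was deeper, with 3299 barcodes, 28284727 UMIs, a median of 6844 UMIs and a range of 501 to 92703. After filtering and removal of doublets, 2828 sham and 3053 nephrectomy nuclei were compared. All intervals are 95% intervals for counting error only, and no difference between the libraries has a replicate check.

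Clustering on genes outside the fixed response lists gave 37 clusters, of which 33 were given a cell type by their markers and grouped into 13 classes. Proximal tubule-like nuclei, which reabsorb most of the filtered load, formed the main class, with 42.5% of sham nuclei (40.6 to 44.3) and 41.3% of nephrectomy nuclei (39.5 to 43.0). Distal convoluted or connecting tubule-like nuclei made up 8.84% of the sham library and 11.8% of the nephrectomy library, a difference of 2.98 points (1.43 to 4.54). Podocyte-like nuclei, from the glomerular filter, were also more frequent in the nephrectomy library, at 2.56% against 1.59%, a difference of 0.964 points (0.232 to 1.70). Thick ascending limb-like nuclei had shares of 13.3% and 11.6%, and the interval of the difference reached 0 (-3.37 to 0.0204 points). Blood endothelial-like nuclei were at 8.06% and 8.22%, and fibroblast-like nuclei, the main source of interstitial matrix, at 2.69% and 2.75%, so no difference was detectable in these classes at this depth. The share of mononuclear phagocyte-like nuclei was 0.955% in the sham library and 0.917% in the nephrectomy library, and that of lymphocyte-like nuclei was 0.460% and 0.557%. A proximal tubule cluster with injury markers held 5 sham and 27 nephrectomy nuclei, and the parietal epithelial-like class held 7 and 22. The labels do not say which part of each kidney was taken, and shares of classes and of tubule segments depend on it. Clusters left unnamed took 15.1% of sham nuclei and 12.7% of nephrectomy nuclei.

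**Figure D1:**
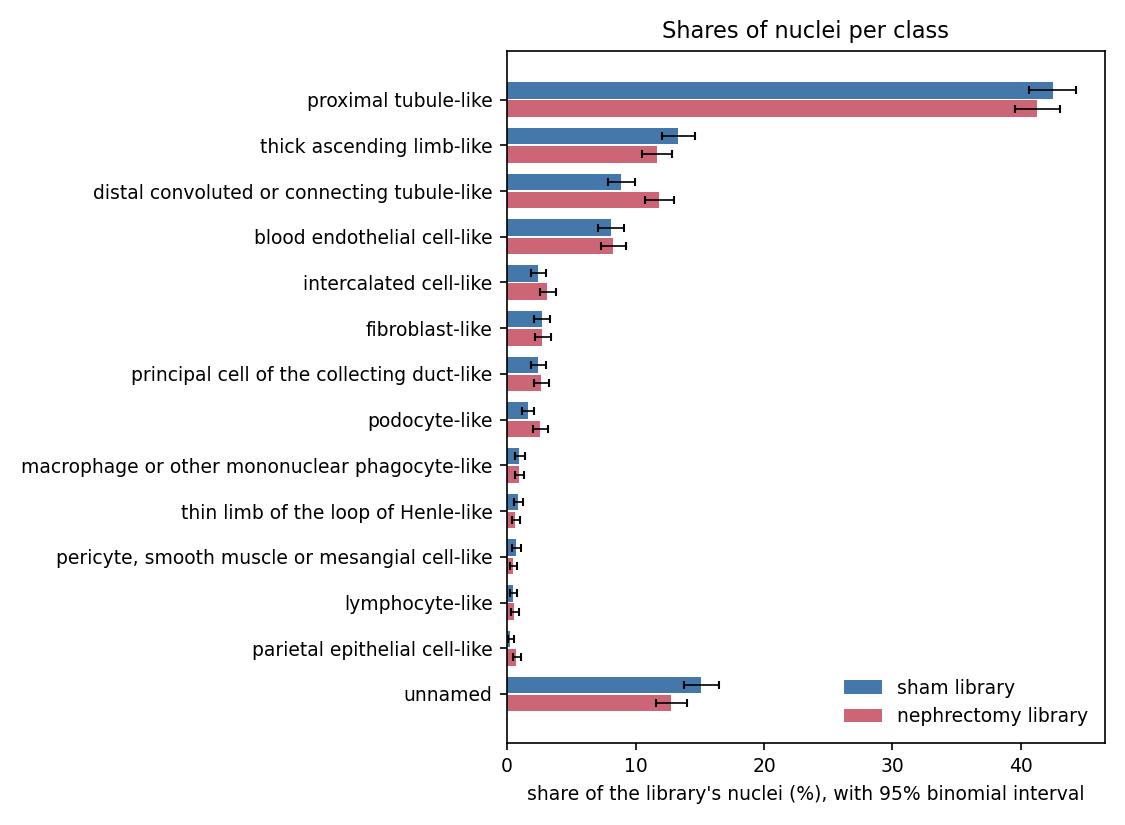
Share of nuclei (%) in each cell class for the sham and nephrectomy libraries, 1 library each, with bars giving the share and lines the exact 95% binomial interval for counting error. Distal convoluted or connecting tubule-like nuclei and podocyte-like nuclei were the compared classes whose difference in share had an interval above 0, at 11.8% against 8.84% and 2.56% against 1.59%.

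The libraries were not spread evenly over the 10 proximal tubule clusters. Clusters 11, 15 and 20 held 484 sham nuclei and 6 nephrectomy nuclei, while clusters 1, 3 and 31 held 220 sham and 825 nephrectomy nuclei. Only 6 proximal tubule clusters held at least 50 nuclei of each library, with 712 sham and 1227 nephrectomy nuclei between them. A cluster that comes mostly from 1 library may be that library, so values within the 6 shared clusters, a comparison added after the data were seen, are plotted for named genes and given in the text where they lay outside the main counting interval of a list. The shared set left out clusters 11, 15, 20 and 31. It still included clusters 1 and 3, with 111 and 104 sham against 429 and 369 nephrectomy nuclei, so uneven clusters were not all removed.

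Csgalnact1 (ENSMUSG00000036356; mm10 chromosome 8, 68356781 to 68735146, minus strand) codes for the glycosyltransferase that starts chondroitin sulfate chains on their core proteins. Its transcripts lay mainly in proximal tubule-like and blood endothelial-like nuclei in both libraries. The gene was higher in endothelial-like nuclei of the nephrectomy library and lower, in summed counts, in proximal tubule-like nuclei. Endothelial-like nuclei held 775 UMIs per 1000000 (CPM; 713 to 841) in the sham library and 974 CPM (910.3 to 1040) in the nephrectomy library, a ratio of 1.26 (1.13 to 1.40). The share of these nuclei with a Csgalnact1 UMI was 67.5% in the sham library and 77.7% in the nephrectomy library, and 41.8% and 50.8% after every nucleus was thinned to 1000 UMIs. Proximal tubule-like nuclei held 152 CPM (145 to 159) and 122 CPM (117 to 128), a ratio of 0.806 (0.753 to 0.862). After thinning that ratio was 0.978, with UMIs in 10.1% of sham and 10.6% of nephrectomy nuclei. Cluster 11, with 223 sham nuclei and 1 nephrectomy nucleus, held 857 of the 1704 sham UMIs, at 302 CPM. Within the 6 shared clusters, with equal weight, the ratio of Csgalnact1 was 0.849, inside the interval over all clusters, and single clusters went either way, with 180 and 200 CPM in cluster 1 and 192 and 136 CPM in cluster 8. Fibroblast-like nuclei had 53 and 88 UMIs, a ratio of 1.23 whose interval spanned 1 (0.864 to 1.76), and after thinning 6.58% and 19.0% of them had a UMI.

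Over the whole library Csgalnact1 stood at 133 CPM (127 to 138) in the sham and 115 CPM (111 to 119) in the nephrectomy library, a ratio of 0.866 (0.820 to 0.915). That direction did not hold when each nucleus had equal weight, where the ratio was 1.04, or after thinning, where it was 1.08. In thick ascending limb-like nuclei, which served as the background, 3.72% of sham and 3.66% of nephrectomy nuclei had a UMI, at median depths of 5859 and 6922 UMIs. Median depths were 2874 and 3263 UMIs in endothelial-like nuclei and 8319 and 9874 in proximal tubule-like nuclei. The Csgalnact1 shares in both of these classes thus lay far above the background.

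Vcan (ENSMUSG00000021614; chromosome 13, 89655312 to 89742509, minus strand), which codes for the large chondroitin sulfate proteoglycan versican, was sparse in both libraries and more abundant in the nephrectomy library. Counts per gene do not resolve its splice forms. The sham library held 36 Vcan UMIs, or 1.94 CPM (1.36 to 2.69), and the nephrectomy library 101 UMIs, or 4.06 CPM (3.31 to 4.94), a ratio of 2.09 (1.42 to 3.15). Nuclei with a UMI made up 0.849% and 2.13% of the libraries, and 0.159% and 0.576% after thinning. Proximal tubule-like nuclei had 12 and 38 UMIs, a ratio of 2.56 (1.31 to 5.38), and thick ascending limb-like nuclei 2 and 14, a ratio of 5.86 (1.35 to 53.1). The latter UMIs lay in 2 sham and 7 nephrectomy nuclei, and after thinning 0 of 359 and 1 of 349 nuclei had one. Fibroblast-like nuclei had only 2 and 6 UMIs and podocyte-like nuclei 0 and 9. In the nephrectomy library this was 12.9 CPM (4.72 to 28.0) and 14.9 CPM (6.80 to 28.2). Both lay above the 2.73 CPM (1.94 to 3.75) of proximal tubule-like nuclei there, but in the sham library the intervals overlapped. Mononuclear phagocyte-like nuclei had 5 UMIs, all in 1 nucleus, and 3 UMIs, at 60.6 and 21.1 CPM. With so few nuclei carrying a UMI, a full ranking of cell types was not possible at this depth. In endothelial-like nuclei, taken as the background at their lower depth, 0.439% and 0.797% of nuclei had a Vcan UMI, against 0.916% and 2.14% of proximal tubule-like nuclei. After thinning, 1 of 225 and 2 of 250 endothelial-like nuclei had one, against 0 of 1163 sham and 3 of 1240 nephrectomy proximal tubule-like nuclei, so Vcan in proximal tubule-like nuclei was not distinguishable from background at equal depth.

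**Figure D2:**
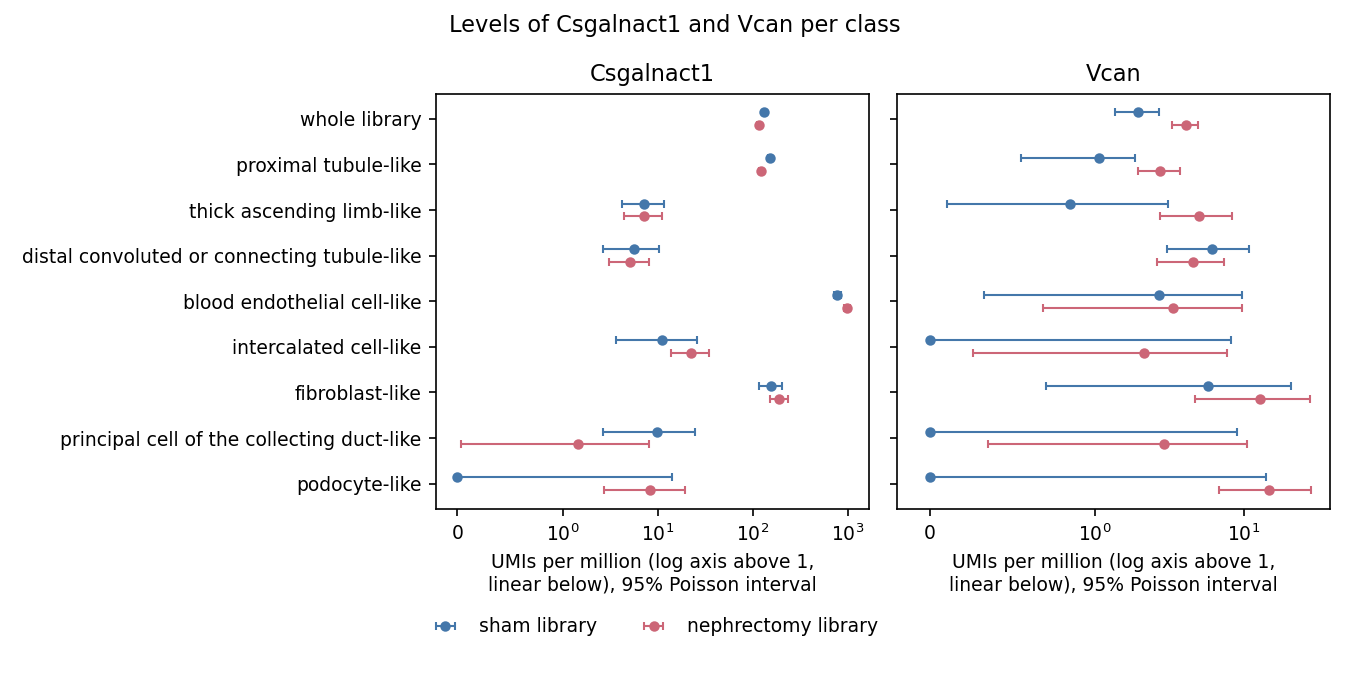
Csgalnact1 and Vcan level (CPM, log axis) per cell class in the sham and nephrectomy libraries, 1 library each, with points for UMIs summed over nuclei and lines for exact 95% Poisson intervals. Csgalnact1 was at its highest in blood endothelial-like nuclei, at 775 and 974 CPM, and Vcan over the whole library was at 1.94 and 4.06 CPM.

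The enzymes that build chondroitin sulfate were, as a list, slightly lower in the nephrectomy library. Of 22 genes for chondroitin sulfate chain synthesis, none was at least 1.5 times higher, 3 were at least 1.5 times lower and 19 lay between, with a median log2 ratio of -0.28 (percentile 0.51 among random lists matched on expression). With equal weight per nucleus that median was -0.0188, so the difference did not hold under that choice. Chpf (1.45) and Chsy3 (1.24) had the highest ratios and Chst7 (0.437) and Chst14 (0.484) the lowest. In proximal tubule-like nuclei, the 4-O-sulfotransferase gene Chst11 was 2.45-fold lower, with 2306 and 1165 UMIs. The list median there was -0.24, within the range of random lists. Fibroblast-like nuclei had a median of 0.24, with Chsy3 at a ratio of 2.32, and principal-like nuclei one of -0.67 over 5 members. Among 11 proteoglycan core genes, Vcan (2.09) and Spock3 (1.69) were highest and Cspg5 (0.504) lowest, for a median of -0.04. Versican partners had a median of 0.16, from the hyaluronan receptor gene Cd44 (2.17) down to the versican-cleaving protease gene Adamts5 (0.465). Lists for glycosaminoglycan breakdown (0.01), heparan sulfate chains (0.11) and basement membrane (-0.04) had medians within the range of random lists over the whole library.

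Fibrillar matrix and myofibroblast genes showed no common direction over the whole library. Of 26 measured, 3 were at least 1.5 times higher, 3 at least 1.5 times lower and 20 between, with a median log2 ratio of 0.03. Tnc, which codes for tenascin C, was higher in the nephrectomy library at a ratio of 4.04 (2.96 to 5.61), as was the membrane metalloproteinase gene Mmp14 at 2.13, with 43 and 123 UMIs. Tnc was among the top 10 genes of the parietal epithelial-like cluster, which held 7 sham and 22 nephrectomy nuclei. Its whole-library ratio is therefore no measure of a change in fibroblast-like nuclei. Thbs2 (0.510) and Fmod (0.466) were lowest. TGF-beta signalling genes had a median of 0.03, with Ltbp2 at 3 sham and 38 nephrectomy UMIs, a ratio of 9.44 (2.99 to 47.8). The integrin gene Itgb6, whose product activates TGF-beta, was 3.03-fold lower.

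In proximal tubule-like nuclei the named genes included ones of fuel metabolism, inflammation and male-biased expression. Pdk4 and Creb3l3, genes of fuel metabolism, were far higher in the nephrectomy library, as were the complement gene C3 and the adhesion gene Vcam1. Pdk4, which codes for the kinase that shuts pyruvate out of mitochondria, was at 15.7 and 155 CPM, a ratio of 9.90 (8.49 to 11.6). Creb3l3 (ENSMUSG00000035041; chromosome 10, 81084324 to 81098874), a fasting-induced transcription factor gene, had 5 and 101 UMIs, a ratio of 16.3. C3 (ENSMUSG00000024164; chromosome 17, 57203970 to 57228136) had 14 and 225 UMIs, a ratio with an interval of 7.58 to 24.2, and Vcam1, an adhesion molecule of maladapted tubule cells, a ratio of 9.70 (5.51 to 18.6). The potassium channel subunit genes Kcnip4 (ENSMUSG00000029088; chromosome 5, 48389502 to 49524907) and Kcnh8 (ENSMUSG00000035580; chromosome 17, 52602709 to 52979194) had ratios of 19.2 and 18.2. The growth factor-regulating protease gene Pappa (14.6), the receptor gene Adgrg2 (7.60) and the cilium gene Cfap77 (7.28) were also higher.

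The lowest gene was Col6a6 (ENSMUSG00000043719; chromosome 9, 105687809 to 105828160), a collagen VI chain gene, with 115 sham and 7 nephrectomy UMIs, 20.3-fold lower. The sodium leak channel gene Nalcn (ENSMUSG00000000197; chromosome 14, 123276634 to 123627144) was 14.6-fold lower. The intervals of the ratios of Col6a6 (0.0194 to 0.105) and Nalcn (0.0333 to 0.127) overlapped, so their order was not settled. The androgen-regulated gene Kap, among the most abundant messages of the male proximal tubule, was at 6627 CPM in the sham and 1217 CPM in the nephrectomy library, 5.45-fold lower. Slc7a13 (ENSMUSG00000041052; chromosome 4, 19818725 to 19842218), a cystine transporter gene of the late proximal segment, was 7.19-fold lower, at 721 and 100.2 CPM. The steroid-metabolising gene Akr1c18 (ENSMUSG00000021214; chromosome 13, 4132615 to 4150654) was 8.17-fold lower and the collagen gene Col19a1 8.10-fold lower. Ldc1 (ENSMUSG00000023120; chromosome 4, 130209109 to 130222401) was 6.88-fold lower, the protease inhibitor gene Pzp 6.61-fold, the glypican gene Gpc5 5.31-fold and the RNA-binding protein gene Igf2bp1 5.29-fold. Kcnip4, Pappa, Akr1c18, Ldc1 and Gpc5 were among the genes used for clustering. Kcnip4, Kcnh8 and Vcam1 were among the top 10 genes of the cluster with injury markers, of 5 sham and 27 nephrectomy nuclei. After thinning C3 was at 4.69, Kcnh8 at 3.13 and Vcam1 at 3.75. Within the 6 shared clusters, with equal weight, the ratio of Kcnip4 was 3.13, that of Kcnh8 5.00, that of Pappa 3.62, that of Vcam1 2.29 and that of Igf2bp1 0.744. Adgrg2 changed direction there, to 0.864, while Pdk4 (6.21), C3 (8.46), Slc7a13 (0.293) and Nalcn (0.362) kept theirs.

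**Figure D3:**
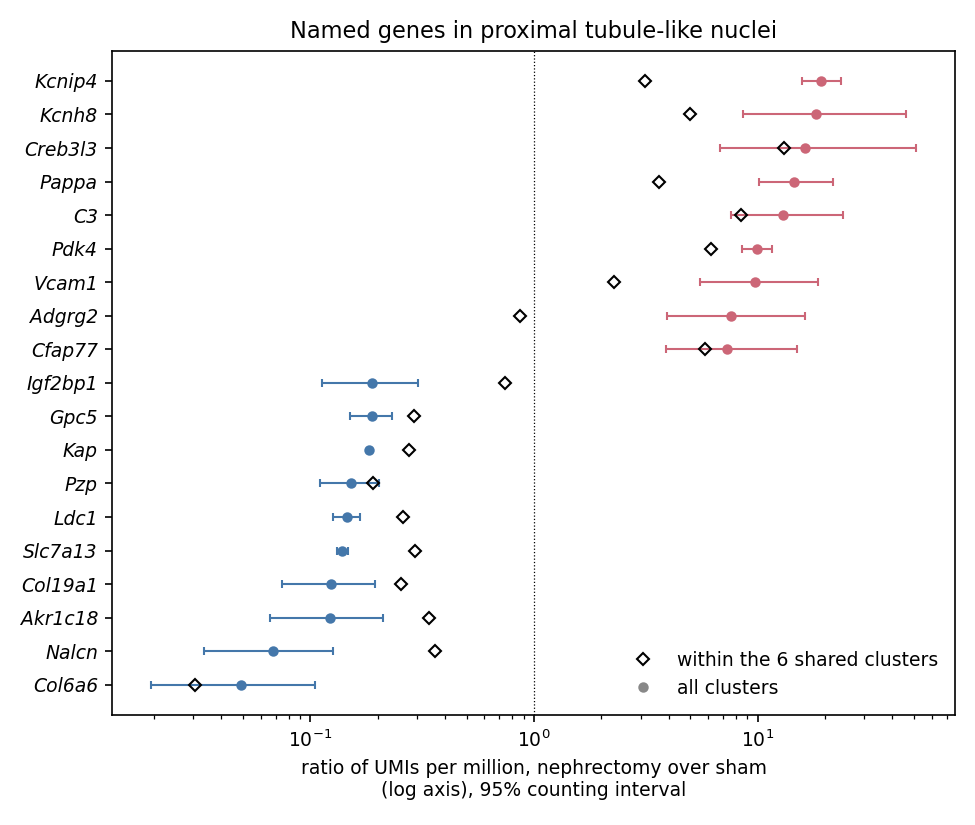
Nephrectomy to sham CPM ratio (log axis) of genes named in proximal tubule-like nuclei, with lines for the exact 95% counting interval, and with diamonds for the same ratio within the 6 shared clusters. Kcnip4 stood at 19.2 over all clusters and at 3.13 within the shared ones, and Pdk4 at 9.90 and 6.21.

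Fatty acid oxidation and peroxisome genes were higher in proximal tubule-like nuclei of the nephrectomy library as a list. Of 30 genes, 16 were at least 1.5 times higher, none at least 1.5 times lower and 14 between, with a median log2 ratio of 0.61 (percentile 100), and of 0.47 within the 6 shared clusters. Pdk4 was near the top of the list, and the acyl-CoA dehydrogenase genes Acadvl (0.750) and Acadm (0.732) were lowest. Glycolysis genes had a median of -0.31, with Pfkp at 1.83 and Gapdh at 0.615, but one of -0.0568 at Leiden resolution 0.5. Mitochondrially encoded transcripts had a median of -0.44, and of -0.15 within the 6 shared clusters, with mt-Nd3 at 1.47 and mt-Nd6 at 0.540. The median mitochondrial share per barcode was 1.39% in the sham and 0.986% in the nephrectomy library. These transcripts lie outside the nucleus. In any class, less cytoplasmic RNA carried over with the nuclei therefore cannot be told apart from a change in the cells. Genes of general proximal tubule transport and metabolism had a median of 0.08, with 31 of 36 between the bounds. The sulfate transporter gene Slc13a1 was 2.66 times higher, with 14339 and 47233 UMIs, and the endocytic receptor gene Lrp2 (0.591) and the anion transporter gene Slc22a7 (0.214) were lowest.

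Male-biased proximal tubule genes were lower, with 11 of 15 at least 1.5 times lower, none higher, and a median of -1.22, below all 10000 random lists. Within the 6 shared clusters it was -1.02. Cyp2e1 (0.974) and Cyp4b1 (0.851) were highest and Kap and Slc7a13 lowest. Female-biased genes had a median of -0.03, with Abcc3 (6.79) and Cyp4a14 (6.04) at the top and Rnf24 (0.489) at the bottom. Genes of the late S3 segment had a median of -0.76, with 8 of 12 at least 1.5 times lower and Slco1a6 (0.968) highest. Within the 6 shared clusters, with equal weight, the S3 median was -0.29. Taken cluster by cluster, the median over these 6 was -0.55, from -0.59 to -0.0457. The S1 and S2 list, for the early segments, had a median of 0.22.

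Chemokine and adhesion genes under NF-kappaB control were higher in proximal tubule-like nuclei of the nephrectomy library, with 12 of 19 at least 1.5 times higher, none lower and a median log2 ratio of 0.71. The monocyte attractant gene Ccl2 had 1 sham and 41 nephrectomy UMIs, a ratio of 33.1 (5.62 to 1340.0), and the macrophage growth factor gene Csf1 had 3 and 52, a ratio of 14.0 (4.54 to 70.1). Cxcl12 (0.945) and Il34 (0.888) were lowest. This median was 0.25 within the 6 shared clusters and 0.06 after thinning. Interferon response genes had a median of 0.62, with 10 of 16 higher, led by Ifit2 (3.71) and Gbp7 (2.61) and with Ifi44 (0.514) lowest, but a median of 0.28 with no UMI minimum. Tubular injury genes had a median of 0.30, with 10 of 25 higher and 4 lower, running from Ccl2 and Vcam1 to Krt7 (0.536) and Itgb6 (0.258). The injury median was 0.11 within the 6 shared clusters and -0.09 after thinning, over the fewer members left. The complement list had a median of -0.10 despite C3 and Cfi (5.52), the latter the gene of a C3b-cleaving protease.

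Heat shock and protein folding genes were lower, with 15 of 19 at least 1.5 times lower, none higher and a median of -1.07 in proximal tubule-like nuclei, or -0.67 within the 6 shared clusters. The inducible chaperone genes Hspa1a (0.155) and Hspa1b (0.155) were lowest, and Hspb1 (1.31) and Asns (1.06) highest. Proliferation genes had a median of -0.57, with 13 of 27 lower, from Brca2 (1.84) to Rrm2 (0.314), and a value of 0.05 after thinning. Single genes outside any moving list included Cyp27b1, which codes for the enzyme that activates vitamin D, at a ratio of 5.43 (4.31 to 6.91), and Cyp24a1, for the enzyme that inactivates it, at 2.77. The phosphate-regulating co-receptor gene Kl was at 0.648. Erbb4, a growth factor receptor gene, was at 3.84 (3.52 to 4.20), the glutamine transporter gene Slc38a3 at 2.06 and the NRF2 target Nqo1 at 1.99. Renin-angiotensin and sodium transport genes (-0.02), vitamin D and phosphate genes (0.02), growth factor genes (0.05), NRF2 genes (0.14) and TGF-beta genes (0.02) had medians within the range of random lists. So did lists for antigen presentation (0.25), immediate early genes (0.25), ammonia and acid handling (0.24), hypoxia (0.08), senescence (0.07) and cysts and dedifferentiation (0.03).

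**Figure D4:**
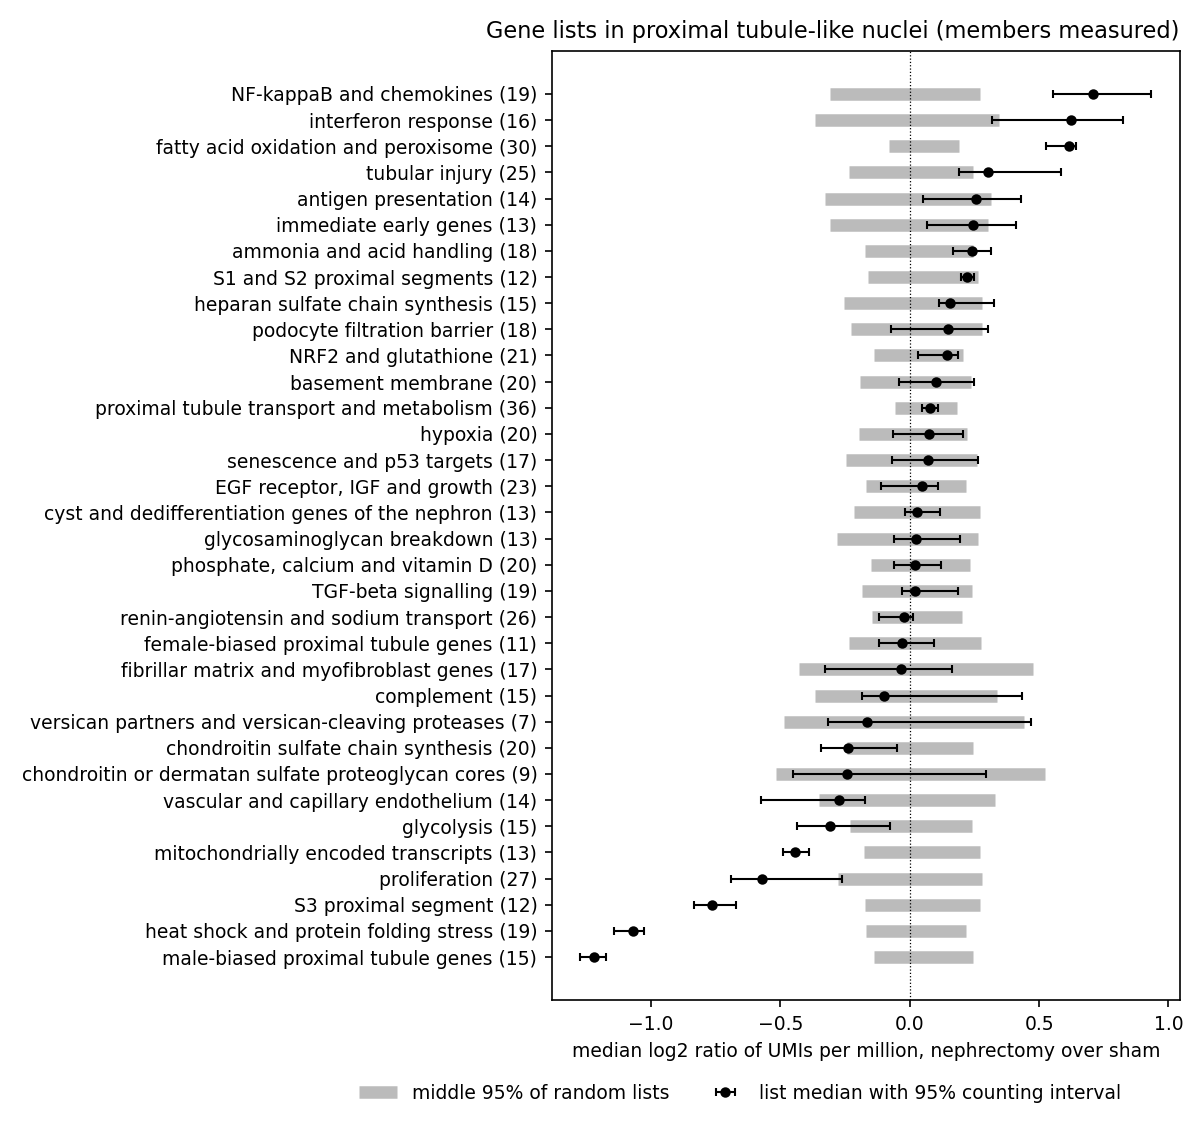
Median log2 nephrectomy to sham ratio of each fixed gene list in proximal tubule-like nuclei, with points for the medians and bars for the central 95% of 10000 random lists matched on mean expression. NF-kappaB, interferon and fatty acid oxidation genes lay above the random range, and male-biased, heat shock and S3 segment genes lay below it.

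Thick ascending limb-like nuclei, which dilute the urine, carried injury markers and cell cycle genes at higher levels in the nephrectomy library. Dcdc2a, a marker of maladapted tubule, was at 11.1 CPM in the sham and 58.4 CPM in the nephrectomy library, a ratio of 5.28 (3.48 to 8.32). Lcn2, which codes for the injury biomarker NGAL, was at a ratio of 6.19 and the secreted chaperone gene Clu at 2.58. The synaptotagmin gene Syt2 was highest at a ratio of 16.4 (6.80 to 51.6), with 5 and 98 UMIs, followed by the sarcoglycan gene Sgcd (11.4) and the catenin gene Ctnnd2 (9.65). After thinning Syt2 was at 3.43 and Sgcd at 3.91, so this order did not hold. Also named were Rad51b (3.43), Adcy10 (3.08), Pde10a (2.85), Pola1 (2.77) and Pappa2 (2.61). Lowest were the synapse gene Insyn2a at 3.15-fold lower, the kinase gene Dclk2 at 2.84-fold and Klhl29 at 2.56-fold, with the peroxiredoxin gene Prdx5 2.38-fold lower. Sgcd, Ctnnd2, Rad51b, Pde10a, Dclk2 and Klhl29 entered the clustering. The ratio of Adcy10 after thinning was 1.03. Among list members, the magnesium channel gene Trpm6 (9.42) and the neural adhesion gene Ncam1 (6.80) also had high ratios. Trpm6 is a marker of the distal convoluted tubule and Ncam1 one of parietal epithelial cells, so RNA carried over from those classes stays open.

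Tubular injury genes in this class had a median log2 ratio of 0.55, with 8 of 17 at least 1.5 times higher and none lower. Proliferation genes had a median of 1.47, with 11 of 16 higher, led by the kinetochore gene Knl1 (3 and 33 UMIs, ratio 9.21, 2.89 to 46.9) and the mitotic motor gene Kif11 (6.70). A few nuclei carried much of that signal, since the 5 nuclei with most proliferation UMIs held 32.0% of them in the nephrectomy and 7.39% in the sham library. Without those nuclei the level was 149 CPM in the sham and 215 CPM in the nephrectomy library. With members of at least 50 UMIs the list median was 0.62. Interferon genes had a median of 0.47 and cyst and dedifferentiation genes 0.38. Immediate early genes were lower, at -0.62, with Ier2 at 0.307 and Jun at 0.505, but at -0.0703 over the 3 members left after thinning. Heat shock genes (-0.83), mitochondrially encoded transcripts (-0.46) and glycolysis genes (-0.34) were also below the random range. The male-biased list was at -1.23 here and at -1.14 after subtraction of free RNA. Kap, at 2982 and 602 CPM in these nuclei, is a proximal tubule message, and whether these nuclei make it was left open. Its ratio was 0.202 here, 0.213 in fibroblast-like and 0.233 in podocyte-like nuclei, near the 0.184 of proximal tubule-like nuclei. RNA carried over from proximal tubule cells could give such ratios, so the list's values outside that class are no measure of a change in other classes. The same list was at -1.28 in distal convoluted or connecting tubule-like nuclei and at -1.10 in endothelial-like nuclei.

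Distal convoluted or connecting tubule-like nuclei showed lower Npas2 and Arntl and higher mitotic genes in the nephrectomy library. Npas2 and Arntl, partners in the activating arm of the circadian clock, were 4.44-fold and 3.33-fold lower, with Npas2 at 45.5 CPM in the sham and 10.3 CPM in the nephrectomy library. Pvalb, which codes for the calcium-binding protein parvalbumin of early distal convoluted cells, was 2.42-fold lower, and the defensin gene Defb1 2.33-fold lower at 1816 and 779 CPM. Among higher genes were the nuclear transport gene Ranbp17 (3.67), the centromere gene Cenpp (3.59), Rab27b (3.38), Rps6ka2 (2.87), the FGF-responsive factor gene Etv4 (2.64) and Spc25, a kinetochore gene (2.48). Ranbp17 changed direction after thinning, to 0.953, and the ratios of Cenpp (1.45) and Etv4 (1.498) were smaller there. Cenpp, Rab27b and Defb1 entered the clustering. Kl, which codes for the FGF23 co-receptor and is made mainly here, was at a ratio of 0.548, and Hbegf had 1 and 25 UMIs, a ratio of 12.8 (2.10 to 526.7). Sesn2, a stress-response gene, had 17 and 83 UMIs and Cyp24a1 was at 3.80.

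Of 19 proliferation genes in this class, 16 were at least 1.5 times higher, none lower, with a median of 1.54. Diaph3 had 1 and 71 UMIs, a ratio of 36.4 (6.33 to 1459), and Knl1 had 2 and 67, a ratio of 17.2 (4.58 to 144.8). The topoisomerase gene Top2a, chosen after its values were seen, had 0 and 62 UMIs. In thick ascending limb-like nuclei Top2a had 1 and 14 UMIs. It went the other way in principal-like (17 and 1), endothelial-like (9 and 0) and proximal tubule-like nuclei (55 and 39). Over the whole library its ratio was 1.07 (0.821 to 1.41). The 5 distal nuclei with most proliferation UMIs held 54.5% of them in the nephrectomy library and 14.2% in the sham library. Without those nuclei the levels of the list were 97.2 and 151 CPM. With equal weight per nucleus the list median was 0.70. After thinning it was -0.0709 over 2 members, and 16.6% of sham and 15.3% of nephrectomy nuclei had a proliferation UMI. Heat shock genes (-0.80), glycolysis genes (-0.40) and mitochondrially encoded transcripts (-0.23) were below the random range, and basement membrane genes above it (0.25), led by Col4a6 (3.76) and Lama3 (2.82).

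In blood endothelial-like nuclei the protocadherin gene Pcdh9, which entered the clustering, was highest at a ratio of 7.25. The ubiquitin ligase gene Mylip (2.27) and the growth factor gene Igf1 at 2.13 (1.64 to 2.79) were among the other higher genes. Eln, which codes for elastin, was 2.63-fold lower and Vegfc, a lymphatic growth factor gene, 2.17-fold lower, and the chaperone genes Dnaja1, at 211 and 84.5 CPM, and Hspa5, 2.38-fold lower, were also among the lowest. Heat shock genes had a median of -0.55, with 7 of 16 lower and none higher. Genes of vascular and capillary endothelium had a median of -0.15 (percentile 2.03), with the sprouting genes Esm1 (0.666) and Angpt2 (0.551) lowest and the adhesion genes Vcam1 (1.18) and Cdh5 (1.12) highest. Heparan sulfate genes had a median of -0.38, with Extl3 at 1.62 and Hs6st3 at 0.223, but one of 0.29 over the 5 members left after thinning. The fibrillar matrix median of -0.88 rested on 6 genes.

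Fibroblast-like nuclei numbered 76 in the sham and 84 in the nephrectomy library, so only large differences were measurable. The complement gene C7, a fibroblast marker, was at 432 CPM in the sham and 3133 CPM in the nephrectomy library, a ratio of 7.25 (6.12 to 8.64). Sulf1, whose product trims sulfates from heparan sulfate, was at a ratio of 5.04 (2.97 to 9.13). Rad51b (5.09), the adhesion gene Kirrel3 (4.98), Sntg1 (3.96), Csmd1 (3.09) and the cadherin gene Fat4 (3.06) were also higher, though after thinning Sntg1 was at 1.18 and Fat4 at 1.27. The small proteoglycan gene Dcn was at 2.60 and Col12a1 at 3.49. Among the lowest were the integrin gene Itga9 at 3.30-fold lower, Kcnb2 at 3.19-fold, the stromal transcription factor gene Tcf21 at 2.70-fold and Adamts5 at 2.37-fold lower. C7, Rad51b, Kirrel3, Sntg1, Csmd1, Fat4 and Itga9 entered the clustering. Fibrillar matrix genes had a median log2 ratio of 0.21 with 15 of 19 between the bounds, from Col5a2 (1.67) and Mmp14 (1.59) to Ccn2 (0.685) and Tagln (0.656). Antigen presentation genes had a median of 0.57, with H2-Ab1 at 3.85 and H2-Aa at 3.21. NF-kappaB genes stood at 0.34, with Relb at 2.10 and Birc3 at 2.07. Heat shock genes (-1.06) and glycolysis genes (-0.74) were below the random range, the latter with a value of 0.08 after thinning.

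The remaining compared classes were small. In intercalated-like nuclei, which handle acid and base, the growth factor gene Pdgfd was at a ratio of 4.80 (3.18 to 7.56), Asah2 at 3.93 (1.88 after thinning) and the glutathione synthesis gene Gclm at 2.63. Myo5a (4.22-fold), Egfem1 (3.78-fold), Rorb (3.27-fold) and the kallikrein gene Klk1 (2.67-fold) were lower there, and these 4 entered the clustering. Egfem1 and Klk1 are markers of the connecting tubule, so RNA carried over from that class stays open, and with equal weight per nucleus Klk1 was at a ratio of 0.904. In principal-like nuclei of the collecting duct, Ranbp3l was at a ratio of 4.05 (2.82 to 5.99) and Nipal1 at 2.80, and the kinase gene Nuak2 was 3.00-fold lower. In podocyte-like nuclei, the ephrin receptor gene Epha6 at 15.8 (6.05 to 58.8) and the splicing factor gene Rbfox1 (6.09), both clustering genes, were highest, with Epha6 at 4.42 after thinning, and Hspa5 was 2.46-fold lower. The 18 filtration barrier genes measured in podocyte-like nuclei all lay within 1.5 times of sham, with a median of -0.02.

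Over the whole library, C3 had the highest ratio at 13.2 (8.22 to 22.6), and Kcnip4 (11.6), the potassium channel gene Kcnmb2 (8.02) and C7 (6.48) were also high. The intervals of Kcnip4 (9.91 to 13.7) and Kcnmb2 (5.36 to 12.5) overlapped that of C3, so their order was not settled. Cyp4a14 (5.29), Cyp27b1 (5.07), Ctnnd2 (4.90), Pdk4 (4.64) and Kctd16 (4.41) were higher as well. Slc7a13 was 7.53-fold lower, Ldc1 7.24-fold, Pzp 6.75-fold, Slc22a7 5.88-fold and Kap 5.60-fold lower. The beta-globin genes Hbb-bt (ENSMUSG00000073940; chromosome 7, 103812524 to 103813996) and Hbb-bs were 6.92-fold and 5.32-fold lower. Their ratios were 0.417 and 0.388 with a stricter filter on nuclei. Cntnap5a, the anion transporter gene Slco1a1 and Erich6b were 5.17-fold, 5.09-fold and 4.87-fold lower. Kcnip4, C7, Ctnnd2, Kctd16, Ldc1 and Cntnap5a entered the clustering. Among lists, tubular injury (0.44), fatty acid oxidation (0.42) and NF-kappaB genes (0.40) were highest, and male-biased (-1.14), heat shock (-1.02) and S3 segment genes (-0.86) lowest. The injury median was 0.0697 after thinning. Vascular and capillary genes had a median of -0.30, with Apln at 0.505, and podocyte filtration barrier genes one of 0.29, with Plce1 at 1.86 and Wt1 at 1.80, beside the larger podocyte-like share, while within podocyte-like nuclei Plce1 was at 1.11 and Wt1 at 1.02.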

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

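All tests here were chosen after the patterns had been seen. For 5 of them the bounds were written before their values were computed, and the tests with Y-linked genes, the transport and metabolism list and ribosomal protein genes were written only after the result was seen. After the first values were known the bounds were also required to hold over the whole spread of clusters or classes, which turned the segment test of fatty acid oxidation from excluded to open. The wording of the 2 tests within clusters was changed once cluster sizes were known.

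Lists that went one way in 1 class and the opposite way in another drew a closer look, and these differences were not tested. Proliferation genes had a median log2 ratio of 1.47 in thick ascending limb-like nuclei and -0.57 in proximal tubule-like nuclei, 2.04 apart, and with 1.54 in distal convoluted or connecting tubule-like nuclei the gap was 2.11. After thinning the proximal tubule median was 0.0450 over 7 members and the distal one -0.0709 over 2 members. The gap between the distal and proximal classes was thus not seen there, but over too few members to settle it. In thick ascending limb-like nuclei, 15.9% (12.25 to 20.1) of sham and 23.2% (18.9 to 28.0) of nephrectomy nuclei had a proliferation UMI after thinning. In proximal tubule-like nuclei these shares were 15.1% and 14.1%. With equal weight per nucleus the proximal tubule median was -0.74 and the distal one stayed positive. Genes of the S3 segment had a median of 0.69 in intercalated-like nuclei. That value lay 1.454 above proximal tubule-like nuclei, 1.785 above thick ascending limb-like nuclei (-1.10), 1.78 above distal convoluted or connecting tubule-like nuclei (-1.09) and 1.205 above endothelial-like nuclei (-0.52). It rested on 9 genes, among them Slco1a6 (2.28) and Cyp7b1 (1.87), and was -0.02 with doublets kept and -0.27 with equal weight per nucleus.

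The lower level of male-biased genes such as Kap and Slc7a13 in proximal tubule-like nuclei was weighed first. A nephrectomy library from a female mouse is excluded, since the median ratio of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y was 1.14. The list's median was -1.05 as the median over the 6 shared clusters, from -1.30 to -0.77, so the list also fell within clusters. Kap, however, fell about as much in thick ascending limb-like nuclei (ratio 0.202) as in proximal tubule-like nuclei (0.184). Free RNA could therefore carry a lower library-wide level into every cluster, so fewer nuclei of the late segment stays open. In the nuclei called proximal tubule-like, the transport and metabolism list did not share the fall, with a median of 0.0766. Several of its members, Lrp2 among them, are also markers that define the class. Nuclei that had lost them would not be counted, so a loss of all proximal tubule transcripts in other nuclei is not excluded. A weaker androgen signal after nephrectomy may be involved, but it was not tested against hormone levels, and a difference between the individual mice stays open.

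The lower level of chaperone genes such as Hspa1a, Hspa1b and Hspa5 was weighed next. After subtraction of the estimated free RNA the median over the 7 other classes was -0.76, though -0.15 in intercalated-like nuclei, which lay inside the random range without subtraction and were left out of the bound. The estimate did not account for Kap, at 2982 CPM in sham thick ascending limb-like nuclei and 5576 CPM in the whole sham library against 9.39% free RNA, so free RNA with more cytoplasmic messages than estimated stays open. Less cytoplasmic RNA carried over with the nuclei could lower such messages, and ribosomal protein genes had a median of -0.39 over the whole library. This cannot be told apart from a change in the tissue, because that value fell between the bounds set and ran from -0.50 in thick ascending limb-like to -0.02 in endothelial-like nuclei.

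The higher level of fatty acid oxidation genes such as Pdk4 in proximal tubule-like nuclei was weighed last. A shift of nuclei between segments cannot be told apart from a change within nuclei, because the median over the 6 shared clusters was 0.33 but single clusters ran from 0.14 to 0.83. A fasting or glucocorticoid response of the animal may contribute, as 15 genes of that response outside the oxidation list had a median of 0.43 (percentile 99.99), with Txnip at 2.60, Zbtb16 at 2.01, Irs2 at 1.98 and Fkbp5 at 1.90. Of the 15, 5 were at least 1.5 times higher and 10 lay between the bounds. That list was also higher in intercalated-like (0.46), distal convoluted or connecting tubule-like (0.32) and fibroblast-like nuclei (0.31). It was at 0.19 in podocyte-like, 0.08 in endothelial-like, -0.06 in principal-like and -0.09 in thick ascending limb-like nuclei. Another time of day at collection also cannot be told apart, because clock output genes had a median of 0.12 over the whole library, between the bounds set, while Arntl (0.632), Npas2 (0.602) and Nfil3 (0.510) were lower and Cry1 (2.03) was higher. In proximal tubule-like nuclei the output list was at 0.02 and 5 clock genes of the Arntl arm at -0.09, both within the range of random lists. Whether nephrectomy itself accounts for these genes stays open with 1 mouse per group.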

How the results depend on the processing

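The tests with doublets by score alone and with only proximal tubule clusters of at least 50 nuclei per library were chosen after the data had been seen, and the other 16 alternatives had been planned. No paired analysis was possible because the groups held 1 library each from different mice. All 72 differences in share between the libraries, for 8 classes, stayed within their main counting interval. The shares themselves moved, as for proximal tubule-like nuclei, which made up 50.2% of sham nuclei with the stricter filter and 40.4% with doublets kept. Of 67 values for Csgalnact1 and Vcan, 61 stayed within the interval, 4 moved and 2 reversed. The endothelial ratio of Csgalnact1 ranged from 1.23 to 1.29, and the whole-library ratio of Vcan from 1.90 to 3.44. Of 160 values for 10 proximal tubule lists outside the random range 137 stayed within the counting interval, 21 moved and 2 reversed, and of 968 values for other lists 72 moved and 16 reversed. For single named genes, 150 of 2071 values moved and 5 reversed, with 70 of those moves after thinning and 34 with equal weight per nucleus. Sntg1 in fibroblast-like nuclei was at 1.18 after thinning. The choice of named genes depended on the UMI minimum: with 50 or 200 UMIs, 15 and 10 of 20 proximal tubule genes and 2 and 6 of 17 endothelial genes were named again.

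The S3 list in intercalated-like nuclei was at -0.0804 with no filter on nuclei and at -0.0761 with expression centred within each library. With doublets kept, that list was at -0.0221 and whole-library Csgalnact1 at 0.916. The proximal tubule median of mitochondrially encoded transcripts was -0.35 with the stricter filter, -0.39 at Leiden resolution 0.5, where glycolysis was at -0.0568, and -0.38 when clustering used all variable genes or left out the cell type markers.

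With equal weight per nucleus, whole-library Csgalnact1 was at 1.04 and the S3 list in intercalated-like nuclei at -0.27, and in proximal tubule-like nuclei glycolysis was at -0.45, proliferation at -0.74, mitochondrially encoded transcripts at -0.50 and male-biased genes at -1.13. After subtraction of free RNA, tubular injury in proximal tubule-like nuclei was at 0.63, and in endothelial-like nuclei the S1 and S2 list was at -0.18 and the transport and fatty acid oxidation lists at -0.28, a value fixed by setting low counts to 3 and no measured reversal.

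After thinning, Csgalnact1 was at 1.08 in the whole library, 0.978 in proximal tubule-like and 3.98 in fibroblast-like nuclei, and whole-library Vcan was at 3.44. Nudc in thick ascending limb-like nuclei (1.03), Ranbp17 in distal convoluted or connecting tubule-like nuclei (0.953) and Rasgef1b (0.879) and Cep128 (0.938) in intercalated-like nuclei reversed. In proximal tubule-like nuclei tubular injury was at -0.0925, S3 genes at -0.87, NF-kappaB genes at 0.0626, proliferation at 0.0450 and male-biased genes at -1.12. In distal convoluted or connecting tubule-like nuclei proliferation was at -0.0709 and the renin-angiotensin list at 0.0716. In intercalated-like nuclei S3 genes were at -0.15 and fatty acid oxidation at -0.0826, in fibroblast-like nuclei glycolysis was at 0.0780, in principal-like nuclei S3 genes were at 0.15 and glycolysis at 0.87, and in podocyte-like nuclei the transport list was at 0.12. Thinned medians use only members with at least 20 UMIs left, so they rest on fewer genes, such as 2 for proliferation in the distal class.

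With no minimum on UMIs, interferon genes in proximal tubule-like nuclei were at 0.28 and vascular genes in fibroblast-like nuclei at -0.0200. Within the 6 shared proximal tubule clusters Adgrg2 was at 0.864, tubular injury at 0.11, S3 genes at -0.29, fatty acid oxidation at 0.47, NF-kappaB at 0.25, heat shock at -0.67, mitochondrially encoded transcripts at -0.15 and male-biased genes at -1.02. For the reversed and moved values the cause was not tested. Depth limits Vcan, with 36 and 101 UMIs in all, and genes in classes of under 100 nuclei.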

Other observations

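No test in this part was planned, and the clock lists were drawn up after the result was seen for Arntl and Npas2.

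The values of clock genes outside the fixed lists varied by class, and differences between classes were not tested. In distal convoluted or connecting tubule-like nuclei, 10 clock output and repressor genes, of which 9 were measured, had a median log2 ratio of 0.57, with Nr1d2 at 2.40 and Dbp at 1.80, while Arntl and Npas2, which had prompted the list, were lower and Cry1 was at 1.66. The output list was also higher in intercalated-like (0.56) and endothelial-like nuclei (0.41). It lay within the range of random lists in fibroblast-like (0.33), principal-like (0.31), podocyte-like (0.12), proximal tubule-like (0.02) and thick ascending limb-like nuclei (-0.02). The vitamin D-inactivating enzyme gene Cyp24a1 was higher in more than 1 class, at 2.77 in proximal tubule-like, 3.83 in thick ascending limb-like and 3.80 in distal convoluted or connecting tubule-like nuclei.

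The red blood cell globin genes Hbb-bs and Hba-a1, the latter chosen after its values were seen, were at 306 and 99.5 CPM in the sham and at 57.5 and 27.3 CPM in the nephrectomy library. In endothelial-like nuclei Hbb-bs was at a ratio of 0.892. Xist had 9 and 20 UMIs in the sham and nephrectomy libraries.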
